A study of Homo sapiens with 12 samples.

How the data were processed

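Single cells of the human embryonic stem cell line HuES8 were profiled after differentiation through neural progenitor cells into neurons or astrocytes, in an unedited line (WT) and in a line lacking WFS1 (WFS1-/-). An effect called genotype here cannot be told apart from any other difference between these lines. Per the labels' protocols, neurons carrying a GFP reporter under the Syn1 promoter and astrocytes carrying a tdTomato reporter under the GFAP promoter were dissociated with different enzymes and sorted singly into 96-well plates. Libraries came from a modified Smart-seq2 reaction in which the oligo-dT primer carried a well barcode and a molecular barcode, so that transcripts were counted as unique molecular identifiers (UMIs) near their 3' ends. Each deposited sample was a plate. The labels gave 4 WT and 4 WFS1-/- neuron plates, split evenly over batches 1 and 2, and 2 WT and 2 WFS1-/- astrocyte plates with no batch.

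The authors deposited UMI counts per gene symbol and well, and these counts were used as deposited, with no normalization by the authors. Per the submitters' processing notes, Trim Galore 0.4.4, cutadapt 1.17, STAR 2.5.3a, UMI-tools 0.5.4 and featureCounts 1.6.2 were used with the hg19 build. The parameters, the gene annotation and any selection of wells before deposit are not given in the sources used here. How reads shared by paralogs, pseudogenes or overlapping genes were counted is also not given, so such genes may have exchanged counts. The tables held 27996 gene symbols, of which 18635 had a UMI in any well. A gene table of assembly GRCh38.p14 was used only for gene names, chromosomes and the order of neighbouring genes, matched 26098 symbols, and gave no coordinates.

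A well was kept as a cell when it had UMIs from at least 1000 genes and at most 30% of its UMIs from mitochondrially encoded genes. Of 1152 wells, 615 were kept, and the mitochondrial limit removed 0 of the wells that passed the gene limit. Because cells were sorted singly into wells, no doublet caller was run. Wells more than 3 median absolute deviations above their plate in log10 UMIs were to be left out in an alternative, and 0 wells met that rule. The median and deviation were taken over all wells of a plate, including those not kept, which widens the spread. The largest cell of neuron WT replicate 1-2 held 22.9% of its plate's UMIs and still did not meet the rule. It therefore does not show that oversized wells were absent. Counts of the kept cells were summed per plate, since cells of a plate are not replicates. Plate sums ranged from 64748 to 1138031 UMIs, and the precision of low genes differed accordingly between plates. Plates of a group were compared by a chi-square test over genes, and the statistic per degree of freedom ranged from 3.34 to 16.5, but variation between cells raises it too, so it does not show whether plates were separate cultures. Each plate was counted as 1 replicate because it was deposited as 1 sample. Plates of the same genotype and batch shared the leading number of their titles and may have come from 1 culture. The p-values therefore measure the spread between plates, part of which may be technical.

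Plate sums were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM scaling, robust dispersions, edgeR's filter on low counts and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. CPM of a gene were scaled over the plates and genes of each comparison, so values of a group differ between comparisons, while marker sums and the ubiquitin values of the closing section used all UMIs of a plate. Neuron genotypes were compared over the 8 neuron plates with batch as a term, and astrocyte genotypes over the 4 astrocyte plates. The difference of the genotype effect between cell types was an interaction contrast over all 12 plates, and that between neuron batches an interaction contrast over the 8 neuron plates. WT astrocytes were also compared with WT neurons, without a batch term, since the astrocyte plates had no batch label. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. For a gene with 0 UMIs in a group no fitted fold is given. Its bound is computed against a floor of 3 counts over the group, and a gene with 1 to 3 UMIs in a group is given as a ratio with its 95% counting interval. Intervals of shares are exact binomial (Clopper-Pearson). Both kinds of interval, and the limits set by a count of 0, cover counting error only. Intervals of medians over a set of genes came from 10000 bootstraps of the genes. Those genes were measured in the same plates, so these intervals do not cover the spread between plates or cultures.

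In total, 25 gene lists and 14 marker lists were fixed from textbook knowledge. Lists with at least 3 tested genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, on log-CPM values with voom weights, with Benjamini-Hochberg adjustment over the lists. Camera with the correlation estimated per list, and fry, which asks whether a list's genes move on balance in the same direction, were run beside it. The estimated setting could be stricter for reasons other than correlation. For the excitatory postsynapse in neurons the estimate was -0.029, below the preset, yet the unadjusted camera p rose from 0.0084 to 0.037. A call lost under this setting is therefore not by itself a sign of correlation between genes. Cells were clustered per cell type with scanpy 1.11.5 (anndata 0.12.19, leidenalg 0.10.2) on 2000 variable genes, 20 components, 15 neighbours and a Leiden resolution of 0.5, with no integration over batches. Genes seen in fewer than 3 cells were left out. The genes that lead a cluster were ranked by the fold of summed CPM over the other cells with 10 CPM added, among genes with a UMI in at least 20% of its cells. A cluster was called X-like only from the fixed marker lists. The test of cluster shares covered only the dividing-cell-like neuron cluster and the astrocyte cluster richest in mesenchymal markers, although all clusters had been planned, because the genes that lead the other neuron clusters differ between the genotypes or batches. The other astrocyte clusters were not compared. Shares, depths and WFS1 were compared by exact two-sided permutation of plates, within batch for neurons.

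The named genes followed a fixed rule. Among genes with an adjusted p under the threshold, at least 10 CPM on average in the higher group and plate values that did not overlap between genotypes (within each batch for neurons), the 10 largest fold changes in each direction were taken. Ribosomal protein genes, pseudogenes, clone-named transcripts, Y-linked genes and XIST were left out of this ranking, and FLJ30901 was counted as clone-named after its value had been seen. Where nothing passed, the 5 lowest p in each direction were taken and are said not to pass. WFS1, up to 4 members of each list that passed, up to 2 members of other lists, the 5 largest fitted changes in each direction for the interactions and the sort comparison, and the marker genes were added. The sample groups, designs, lists, naming rule and most processing alternatives were chosen before the data were examined. In the text, a gene outside this rule is said to have been chosen after its values were seen.

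The steps were tested on simulated counts drawn from a pooled mean per gene over the plates compared, with the real plate depths. Apart from the change given, the simulation held no difference between batches or cell types. Its recovery shares therefore need not hold for genes near 0 in a group. In the neuron comparison, over 5819 genes, 77.3% of genes given a log2 change of 2 and 11.1% of those given a log2 change of 1 were recovered, and 1 of 79 calls was false. In the astrocyte comparison, over 7041 genes, the same shares were 7.5% and 0%, and 1 of 8 calls was false. In the difference between cell types, over 8800 genes, they were 8.3% and 0%, with 1 of 9 calls false. In the difference between batches, over 7421 genes, they were 15.6% and 0%, with 0 of 15 false. In the sort comparison, over 8288 genes, they were 39.3% and 4.5%, with 3 of 42 false. A small count of passing genes in a comparison with low recovery therefore sets only a loose limit on what changed.

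The alternatives were DESeq2 1.42.0 as the test, DESeq2's size factors in edgeR, no filter on low counts, all wells, a stricter cell filter (at least 2000 genes and at most 15% mitochondrial UMIs), cells thinned to 2000 UMIs (612 cells, with 3 shallower cells left out), each plate left out in turn, no batch term, plates sharing the leading number summed, each neuron batch alone, a replicate block, Leiden resolution 1.0 and the estimated correlation in camera. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for counts, permutations and plots.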

Results

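WFS1 encodes a glycoprotein of the endoplasmic reticulum membrane, and its loss causes Wolfram syndrome, a recessive disorder of diabetes, optic atrophy and psychiatric disease. Neurons and astrocytes derived from HuES8 embryonic stem cells, with and without WFS1, were sorted singly and sequenced. Of 1152 wells, 615 held a cell that passed: 237 WT neurons, 203 WFS1-/- neurons, 101 WT astrocytes and 74 WFS1-/- astrocytes. The passing share of a plate ranged from 18.8% to 92.7%, with means ± SD over plates of 61.7 ± 23.4% in WT and 52.9 ± 24.4% in WFS1-/- neurons, and 52.6 ± 3.68% in WT and 38.5 ± 23.6% in WFS1-/- astrocytes.

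Passing WT and WFS1-/- neurons had plate medians of 6306 ± 2828 and 5913 ± 2334 UMIs (exact permutation within batch, p = 0.722, 4 plates each) and of 1715 ± 375 and 1544 ± 214 genes (exact permutation p = 0.389). Mitochondrially encoded transcripts made up 4.54 ± 0.642% of UMIs in WT and 6.95 ± 2.13% in WFS1-/- neurons (exact permutation p = 0.111, where 0.0556 was the smallest p possible). In batch 1 the WFS1-/- plates had 4.68% and 5.60% and the WT plates 4.82% and 3.58%, and in batch 2 the WFS1-/- plates had 8.91% and 8.63% and the WT plates 4.92% and 4.83%. Astrocytes were deeper in the WT plates, with 18960 ± 5609 UMIs and 3710 ± 254 genes, than in the WFS1-/- plates, with 9502 ± 598 UMIs and 2410 ± 718 genes (exact permutation p = 0.333 for each, the smallest that 2 against 2 plates can give). Their mitochondrial shares were 5.39 ± 1.25% and 5.92 ± 2.09% (exact permutation p = 1).

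Transcripts of WFS1 itself were too few to show the edit. The WT neuron plates held 0, 2, 10 and 2 UMIs and the WFS1-/- neuron plates 3, 0, 0 and 1, or 6.33 ± 5.81 and 2.52 ± 3.98 CPM (exact permutation p = 0.278). A plate with 0 of 286901 UMIs still allows up to 10.5 CPM. In astrocytes WFS1 had 21 and 16 UMIs in the WT plates and 2 and 19 in the WFS1-/- plates, or 17.8 ± 0.926 and 21.2 ± 18.5 CPM (exact permutation p = 1; edgeR QL log2 fold change 0.41, SE 0.71, adjusted p = 0.996 by BH). Counts near the 3' end can persist after a frameshift, so these values neither support nor contradict the genotype labels.

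The sorted populations carried the transcripts of their intended cell types. In WT neurons DCX, a microtubule protein of young neurons, had 1024 CPM against 6.11 in WT astrocytes (log2 fold change astrocytes over neurons -7.35, SE 0.47), STMN2, which regulates neurite growth, 2811 against 100 CPM (-4.80), and the dendritic protein gene MAP2 952 against 163 CPM (-2.55). The synaptic vesicle genes SYT1 (716 against 129 CPM) and SNAP25 (88.5 against 7.42 CPM) and the tubulin gene TUBB3 (577 against 177 CPM) were also higher in neurons. SLC17A6, the vesicular glutamate transporter of excitatory neurons, had a ratio of 59.9 (interval 20.1 to 293), MYT1L of 232 (79.1 to 1130) and ELAVL4 of 165 (56.1 to 803), each from 3 UMIs in astrocytes. In WT astrocytes GFAP, the filament gene whose promoter drove the sorted reporter, had 2944 CPM against 13.7 in neurons (7.71), and the surface receptor CD44 2191 against 12.6 CPM (7.53). The calcium-binding protein gene S100B had 390 against 27.1 CPM (3.68), SPARCL1 854 against 35.3 CPM (4.33), the water channel AQP4 78.0 against 5.80 CPM (3.33) and glutamine synthetase GLUL 380 against 35.7 CPM (3.35).

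The astrocyte plates also held transcripts of fibroblasts and smooth muscle. The fibrillar collagen COL1A1 had 3578 CPM in WT astrocytes against 20.1 in WT neurons (log2 fold change 7.30), COL3A1 343 against 24.2 CPM (3.95), and TAGLN, an actin-binding protein of smooth muscle, 825 against 24.5 CPM (4.77). Genes with 0 counts in neurons included IGFBP7 (at least 148-fold), ITGA8 (62.2), COL6A3 (57.4), HTRA1 (46.0) and MFAP4 (41.5), each a bound against a floor of 3 counts over the group. Genes with 0 counts in astrocytes included EPHA5 (at least 152-fold), RPS6KL1 (115) and RUNDC3B (74.0). RAB3C and SCG3, genes of vesicle and granule release, had ratios of 1102 (interval 197 to 43568) and 989 (177 to 39119) over a single UMI in astrocytes. The growth cone gene GAP43 did not pass (-0.30, adjusted p = 0.375), and NEFL, a neuronal filament gene, was higher in astrocytes (1.71, adjusted p = 1.17e-04). By edgeR QL, 2760 of 9094 genes passed at a BH-adjusted p under 0.05, 1616 higher in WT astrocytes and 1144 higher in WT neurons, and 3713 had an unadjusted p under 0.05. For WT astrocytes against WT neurons only 2 astrocyte plates could be used, and without astrocyte WT replicate 1-1 or 1-2 the count was 1372 or 1601. The astrocyte plates had no batch label, so a batch difference between the cell types could not be assessed.

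**Figure D1:**
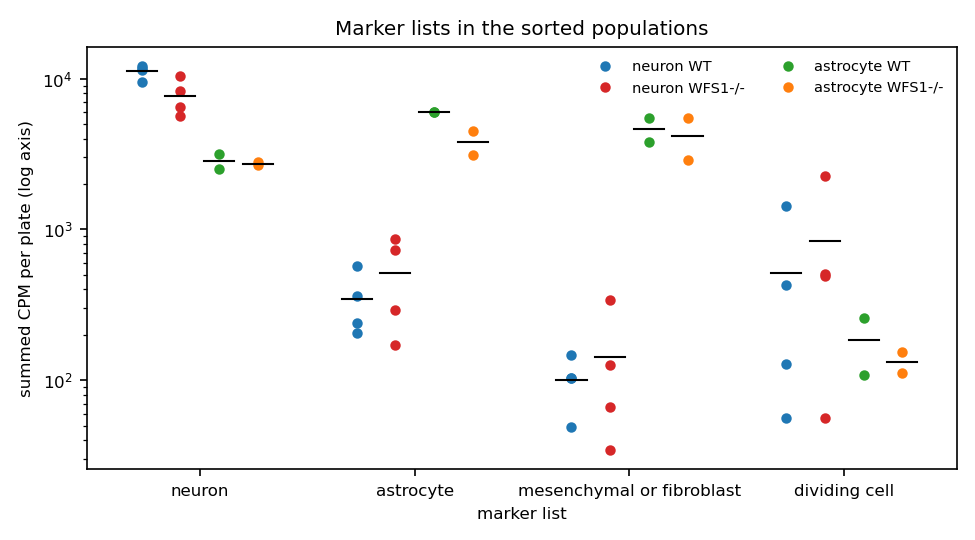
Summed CPM (log axis) of the neuron, astrocyte, mesenchymal or fibroblast, and dividing cell marker lists, 1 point per plate. Bars are means of the plates of each group.

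Summed marker lists described each group further. In WT neurons, WFS1-/- neurons, WT astrocytes and WFS1-/- astrocytes, in that order, the neuron list had 11172 ± 1191, 7730 ± 2098, 2842 ± 486 and 2736 ± 105 CPM. The astrocyte list had 345 ± 166, 513 ± 334, 6012 ± 26.5 and 3791 ± 957 CPM and the mesenchymal or fibroblast list 101 ± 40.1, 142 ± 137, 4645 ± 1203 and 4175 ± 1798 CPM. Excitatory neuron markers had 111, 127, 13.3 and 19.6 CPM, inhibitory neuron markers 127, 113, 39.4 and 76.4 CPM, and markers of monoaminergic, cholinergic and motor neurons 23.8, 6.60, 0.879 and 0 CPM. Dividing cell markers had 513 ± 638, 832 ± 982, 185 ± 107 and 133 ± 29.6 CPM, neural progenitor markers 359, 742, 362 and 498 CPM, neural crest markers 457, 680, 144 and 82.1 CPM, and markers of pluripotent cells 3.37, 37.1, 6.0 and 1.80 CPM. In neuron clusters 1, 2 and 3 below, the neural crest sums of 461, 1067 and 364 CPM held 448, 1046 and 344 CPM of TFAP2B. In cluster 4 TFAP2B gave 219 of 598 CPM. The neural crest sum in neurons was thus largely 1 gene and does not set a cell type. Low sums came from the oligodendrocyte list (1.30, 9.34, 49.7 and 23.6 CPM), choroid plexus (17.0, 34.3, 41.0 and 44.4 CPM), endothelium (5.75, 9.26, 60.2 and 40.5 CPM) and microglia and blood (0, 4.25, 0.439 and 0 CPM).

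Single genes of varied function passed between WFS1-/- and WT neurons. UBB, a polyubiquitin gene, rose from 41.0 ± 22.9 to 962 ± 206 CPM (log2 fold change 4.43, SE 0.31, adjusted p = 3.02e-10, 4 plates per genotype). A part of this rise may be reads shared with other ubiquitin genes. SPRY1, an inhibitor of receptor tyrosine kinase signalling, rose from 51.8 to 316 CPM (2.70, SE 0.32, adjusted p = 5.80e-06). The collagen receptor kinase DDR1 rose from 144 to 570 CPM (2.01, SE 0.27), and TUBB, a beta-tubulin, from 1105 to 2831 CPM (1.37, SE 0.17). ABCF1, which acts in translation, rose from 187 to 536 CPM (adjusted p = 6.67e-04). ABCF1, TUBB and DDR1 lie in a stretch of 15 tested neighbours on chromosome 6 that were all higher in WFS1-/- neurons. Within batches 1 and 2 the log2 fold changes were 4.86 and 4.13 for UBB, 2.46 and 2.89 for SPRY1, 2.64 and 1.51 for DDR1, 1.41 and 1.33 for TUBB, and 1.79 and 1.22 for ABCF1, whose adjusted p in batch 2 alone was 0.0585.

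Among genes that fell, PCSK1, the convertase that cleaves prohormones in secretory granules, had 180 UMIs in WT and 0 in WFS1-/- neurons (at least 53.3-fold lower against a floor of 3 counts over the group, adjusted p = 4.84e-05), and WT plates had 48.3 and 231 CPM in batch 1 and 113 and 57.8 CPM in batch 2. CALB1, the calcium buffer calbindin, fell from 156 ± 65.1 to 11.2 ± 8.11 CPM (adjusted p = 8.23e-05, with log2 fold changes of -3.68 and -3.41 in the batches alone). The ephrin receptor EPHA5 fell from 217 to 30.5 CPM (-2.59, SE 0.39, and -2.57 and -2.60 by batch). The zinc finger gene BNC2 fell from 97.1 to 6.81 CPM (-4.21, SE 0.66, and -4.96 and -3.90 by batch) and the developmental gene MAB21L2 from 117 to 10.7 CPM (-3.27, SE 0.59). CSAG1 had 68 UMIs in WT and 1 in WFS1-/- neurons, a ratio of 60.4 (interval 10.5 to 2419, adjusted p = 0.00646). It lost its call without WFS1-/- replicate 4-2 (adjusted p = 0.113). PDZRN3, a ubiquitin ligase gene, fell from 139 to 22.1 CPM (-2.40, SE 0.48, and -2.08 and -2.63 by batch), and without WT replicate 3-1 or WFS1-/- replicate 4-1 its adjusted p was 0.0568.

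The remaining named genes passed by less. CNTN2 and EPHA4, surface proteins of axons, had log2 fold changes of 2.98 (SE 0.70) and 1.78 (SE 0.37), the elongation factor homologs TCEAL7 and TCEAL2 of 2.44 (SE 0.56) and 2.08 (SE 0.47), and the small GTPase RND3 of 1.62 (SE 0.38). OPRM1, the mu opioid receptor, fell by 2.97 (SE 0.71), SLC8A1, a sodium and calcium exchanger, by 2.45 (SE 0.54), and PDIA6, a disulfide isomerase of the endoplasmic reticulum, by 2.34 (SE 0.58) on the log2 scale. Each of these 8 lost its call when any of at least 5 plates was left out. OPRM1 and PDIA6, whose adjusted p was 0.0405 and 0.0499, lost theirs whichever of the 8 plates was left out. Single plates stood out for CNTN2 (196 CPM in WFS1-/- replicate 2-2) and TCEAL2 (201 CPM in WFS1-/- replicate 4-1). By batch the log2 fold changes were 3.61 and 2.52 for CNTN2, 2.45 and 1.28 for EPHA4, 1.89 and 2.80 for TCEAL7, 1.95 and 2.19 for TCEAL2, 1.53 and 1.69 for RND3, -3.31 and -2.04 for SLC8A1, and -1.78 and -2.91 for PDIA6. Of these, only EPHA4 in batch 1 and TCEAL7 in batch 2 passed within a batch.

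In all, 42 of 6296 genes passed in neurons by edgeR QL at a BH-adjusted p under 0.05, 17 higher and 25 lower in WFS1-/-, and 559 had an unadjusted p under 0.05. In both batches 610 genes, or 9.69% where chance gives 5.56%, had plates that did not overlap between genotypes, among them 40 of the 42. Summing the plates that share a leading title number, and so may share a culture, left 2 genes, UBB and SPRY1, while without WT replicate 3-1 there were 24. With the dividing-cell-like cluster described below left out, 57 genes passed, 33 of them among the 42.

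**Figure D2:**
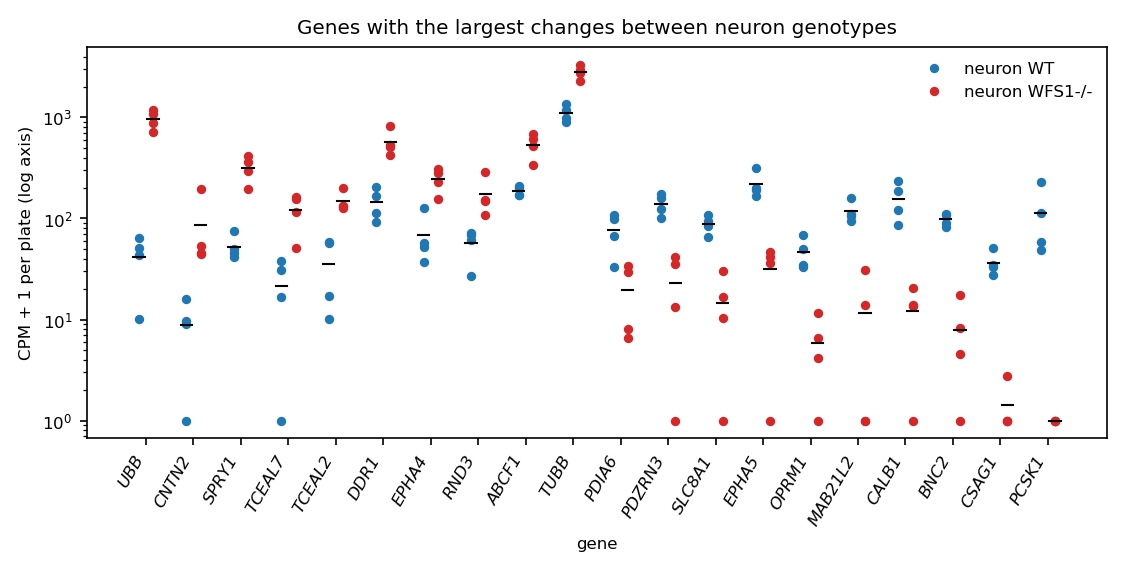
CPM plus 1 (log axis) of 20 genes in each of the 4 WT and 4 WFS1-/- neuron plates. Points are plates and lines are group means.

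Genes of the synapse were lower in WFS1-/- neurons as groups. Of 28 tested genes of the presynapse and vesicle release, 26 had negative fold changes (median log2 fold change -0.58, camera adjusted p = 2.77e-08 by BH over the lists; adjusted p = 0.100 with an estimated correlation). Only SYT4, a synaptotagmin of dense-core vesicles, passed by itself (-1.29, SE 0.28, adjusted p = 0.0191, and -1.76 and -0.96 by batch), and its call was lost when any of 5 plates was left out. PCLO, which organizes the active zone (-1.11), and the vesicle GTPase gene RAB3C (-0.78) did not pass. The inhibitory synapse list was negative in 9 of 9 genes (median -0.68, camera adjusted p = 4.22e-04; adjusted p = 0.165 with an estimated correlation). Its members, none passing, included the GABA receptor subunits GABRA3 (-2.08) and GABRB2 (-1.02) and the glycine receptor subunit GLRA2 (-1.94).

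The excitatory postsynapse list had 10 of 15 genes negative (median -0.63, mean -0.34, camera adjusted p = 0.0404; adjusted p = 0.179 with an estimated correlation) and no member that passed. GRIA2, an AMPA receptor subunit, had 681 CPM in WT and 403 CPM in WFS1-/- neurons (-0.99, adjusted p = 0.109), the NMDA receptor subunit GRIN2B had a log2 fold change of -0.97, the scaffold DLG2 of -1.85 and the kinase CAMK2B of -0.67. This call was lost in batch 2 alone (adjusted p = 0.340), with a replicate block (0.0566), without WT replicate 1-1 (0.167) and without WFS1-/- replicates 2-1 (0.269), 2-2 (0.074) or 4-1 (0.065). With mitochondrial and ribosomal genes left out the median was -0.62 and the unadjusted p 0.0093 (0.0084 before), and the adjusted p rose to 0.059 because those 2 lists left the adjustment. Adjusted over the list alone, 5 presynaptic, 4 inhibitory and 1 excitatory member passed, all lower in WFS1-/-.

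The synaptic medians lay further from 0 in batch 1, and cells of a cluster called dividing-like, described below, were unevenly spread over the same plates. In batches 1 and 2 the medians were -0.70 and -0.41 for the presynapse, -1.06 and -0.74 for inhibitory synapses, and -0.78 and -0.18 for the excitatory postsynapse. Dividing-like cells made up 41.0% of WFS1-/- and 6.17% of WT neurons in batch 1 but 4.86% and 7.54% in batch 2. Without them the medians were -0.33, -0.65 and -0.22, and the excitatory list no longer passed (camera adjusted p = 0.135). Summed neuron markers were also lower in WFS1-/- plates, as given above. Other splits of the 8 plates gave up to 8 passing lists, against 5 for genotype.

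The lists of mitochondrially encoded and ribosomal protein genes were higher in WFS1-/- neurons at the preset correlation, but neither passed with an estimated correlation. All 14 mitochondrially encoded genes had positive fold changes (median 0.69, camera adjusted p = 8.72e-20; adjusted p = 0.154 with an estimated correlation), and 3 passed: MT-ATP6, a subunit of ATP synthase (1269 to 3052 CPM, adjusted p = 0.00200), the cytochrome b gene MT-CYB (3147 to 5750 CPM, 0.86, SE 0.16) and the complex I gene MT-ND4 (1915 to 3251 CPM, 0.76, SE 0.17). MT-CO3 did not pass (0.74, adjusted p = 0.0662). The list's median was 0.17 in batch 1 (adjusted p = 0.075) and 0.95 in batch 2, and MT-ATP6 and MT-CYB had adjusted p = 0.281 and 0.136 in batch 1 alone. MT-ND4 had 0.67 and 0.86 by batch and lost its call when any of 5 plates was left out. Ribosomal protein genes were positive in 73 of 76 cases (median 0.41, camera adjusted p = 4.31e-24; adjusted p = 0.165 with an estimated correlation), with medians of 0.44 and 0.39 in the batches and no single gene passing. RPS27 (0.75, adjusted p = 0.0628) and RPL13 (0.72, adjusted p = 0.0572) came closest. Adjusted over the list alone, 10 mitochondrially encoded and 12 ribosomal genes passed, all higher. The mitochondrial share of UMIs was higher in both WFS1-/- plates of batch 2, as given above.

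Other lists did not pass in neurons, though some of their members did. In the secretory granule and neuropeptide list (median log2 fold change -0.25, adjusted p = 0.0955) PCSK1 and the granin SCG2 fell (842 to 286 CPM, -1.36, SE 0.26), as did CHGA, another granin, named after its values were seen (-1.73, adjusted p = 0.0367, lost when any of 6 plates was left out). By batch SCG2 had -2.13 and -0.71, and without WFS1-/- replicate 2-1 or 2-2 its adjusted p was 0.0558 or 0.0726. In the calcium handling list (-0.17, adjusted p = 0.0825) CALB1 and SLC8A1 fell, and in axon growth and guidance (-0.24, adjusted p = 0.33) CNTN2 and EPHA4 rose and EPHA5 fell. JUN, an immediate early transcription factor, rose from 300.5 to 717 CPM (1.24, SE 0.22, with 1.23 and 1.26 by batch), while its list of immediate early and dissociation genes did not pass (0.31, adjusted p = 0.0955). The list of endoplasmic reticulum chaperones and associated degradation, the compartment of WFS1, did not pass (0.21, adjusted p = 0.220), nor did the integrated stress response (0.53, adjusted p = 0.0836), where 11 of 12 genes were positive and DDIT4 (1.35) and SHMT2 (1.02) led without passing. The stress response did pass without dividing-like cells (adjusted p = 0.0446) and without WT replicates 1-2 (0.0459) or 3-1 (0.0451) or WFS1-/- replicate 4-1 (0.0438), so it lay near the threshold. Immediate early genes passed without WT replicates 1-2 (0.0459) or 3-1 (0.0101), and the secretory list without WT replicate 1-2 (0.0459).

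For the other lists in neurons the median log2 fold changes and camera adjusted p were 0.12 and 0.0637 for glycolysis, 0.47 and 0.0749 for astrocyte factors acting on synapses, 0.35 and 0.0955 for the hypoxia response, 0.11 and 0.130 for nuclear oxidative phosphorylation, -1.0 and 0.130 for interferon response and MHC class I, 0.28 and 0.167 for cholesterol synthesis, 0.28 and 0.314 for autophagy and lysosome, and 1.63 and 0.548 for forebrain identity. They were -0.13 and 0.588 for glutamate uptake, -0.13 and 0.588 for mitochondrial dynamics and mitophagy, 0.27 and 0.588 for reactive astrocyte genes, 0.26 and 0.823 for extracellular matrix, and 0.07 and 0.588 for p53 targets, whose mean of -0.03 had the opposite sign. Over both batches only 4 of 24 reactive astrocyte, 4 of 27 interferon and 3 of 14 forebrain genes were tested. For the matrix it was 9 of 30 genes and for synapse factors 8 of 25. The medians of several of these lists had opposite signs in batches 1 and 2, but no list was tested for a difference between batches. Each batch was filtered on its own, so its medians need not rest on the same genes. The calls by batch used the preset correlation only. Medians and adjusted p in batch 1 and then batch 2 were 1.37 (0.00108) and -0.95 (0.0311) for reactive astrocyte genes, 1.32 (0.0217) and -0.65 (0.0319) for the matrix, 0.59 (0.0266) and -2.85 (1.10e-06) for interferon response, and 2.19 (1.36e-04) and -0.97 (0.417) for astrocyte factors acting on synapses. Astrocyte markers summed to 862 and 726 CPM in the WFS1-/- plates of batch 1 against 206 and 238 CPM in its WT plates. Without the dividing-like cells described below, the medians over both batches were -0.47 for reactive genes, 0.07 for the matrix, -1.66 for interferon response and 0.10 for synapse factors. Cholesterol synthesis passed in batch 1 alone (0.00651), and glycolysis (5.56e-04), hypoxia (0.0260) and the secretory list (0.0473) in batch 2 alone. Leaving out a plate also made calls. Glycolysis passed without WT replicates 1-1 (0.0441) or 1-2 (0.00868) or WFS1-/- replicates 2-1 (0.0243), 2-2 (0.0139) or 4-1 (0.0223), and synapse factors without WT replicates 1-2 (0.00868), 3-1 (0.00874) or 3-2 (0.0305) or WFS1-/- replicate 4-1 (0.0205). Interferon response passed, lower in WFS1-/-, without WT replicate 1-1 (2.44e-04) or WFS1-/- replicates 2-1 (1.06e-04), 2-2 (0.00269) or 4-2 (0.0302). Nuclear oxidative phosphorylation passed without WT replicate 3-1 (0.0263) or WFS1-/- replicate 4-2 (0.0212), and hypoxia without WT replicate 1-2 (0.0459). Without dividing-like cells glycolysis (0.0258) and cholesterol synthesis (0.0219) passed, and with all wells synapse factors did (0.0170). The hindbrain list had too few tested genes. Adjusted over the list alone, axon growth and guidance had 3 genes higher and 4 lower, calcium handling 1 higher and 3 lower, secretory granule and neuropeptide 4 lower, immediate early genes 1 higher, the endoplasmic reticulum list 1 lower (PDIA6), and mitochondrial dynamics 1 lower, FUNDC1 (-1.53).

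**Figure D3:**
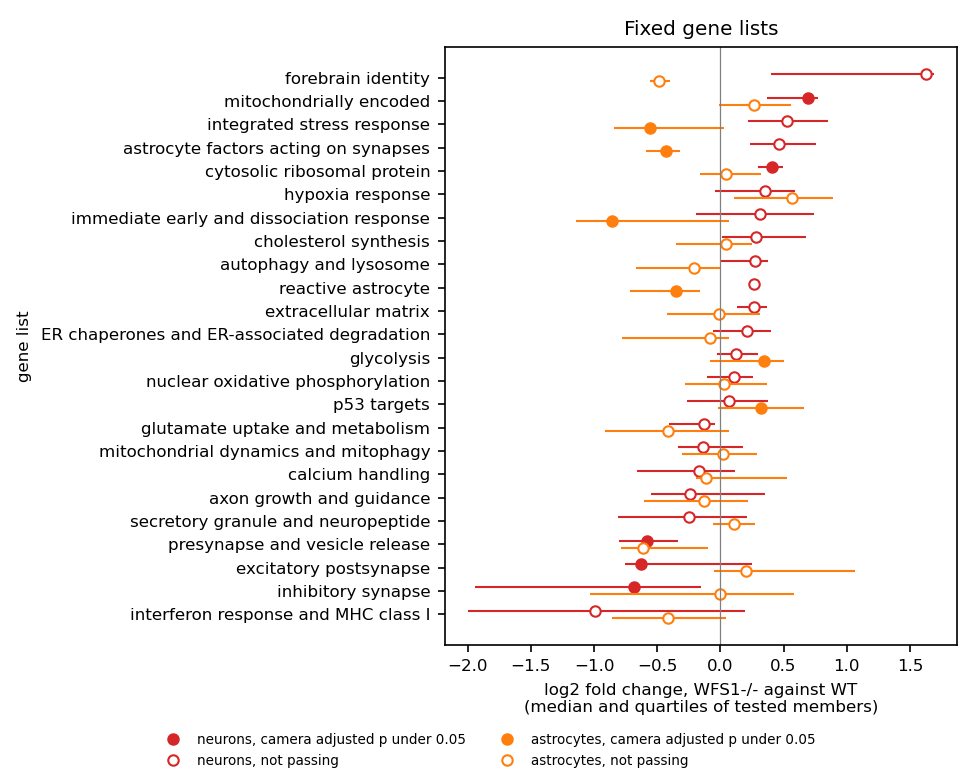
Median log2 fold change of WFS1-/- over WT for the tested members of each gene list, with bars from the lower to the upper quartile, in neurons (red) and astrocytes (orange). Filled points mark lists with a camera adjusted p under 0.05 at the preset correlation.

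In astrocytes no gene passed between genotypes, and the genes with the lowest p are given as values. CPM are scaled over the plates of each comparison, so WT levels differ from those given above. Those higher in WFS1-/- were the smooth muscle actin ACTG2 (8.94 and 18.2 CPM in the WT plates, 32.2 and 689 CPM in WFS1-/- replicates 2-1 and 2-2, log2 fold change 4.77, and 1.22 without replicate 2-2), the neuronal glucose transporter SLC2A3 (48.5 and 173 CPM, 1.80), S100B (313 and 827 CPM, 1.40) and the collagen-binding integrin ITGA2 (36.6 and 145 CPM, 1.93). The small nucleolar RNA host gene SNHG3 had 17.0 and 35.4 CPM in the WT plates but 2469 and 19.5 CPM in WFS1-/- replicates 2-1 and 2-2, and its log2 fold change of 5.56 turned to -0.39 without replicate 2-1. That plate had only 21 passing cells. Those lower were GFAP (2372 and 737 CPM, -1.69, SE 0.33), whose reporter defined the sort, FOS, an immediate early gene (795 and 234 CPM, -1.76, SE 0.35), and COL3A1 (278 and 45.5 CPM, -2.58). The calcification inhibitor MGP had 118 UMIs in WT and 0 in WFS1-/- plates, or at least 15.2-fold lower against a floor of 3 counts over the group, and the tight junction gene CLDN10 had 63 and 0 UMIs, or at least 8.13-fold lower.

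By edgeR QL 0 of 7530 genes passed in astrocytes at a BH-adjusted p under 0.05 (lowest adjusted p = 0.995), 251 had an unadjusted p under 0.05, and DESeq2 gave 0 genes with 180 unadjusted. Plates did not overlap between genotypes for 2685 genes, or 35.7% where chance gives 33.3%. The test of astrocytes WFS1-/- against WT had little power with 2 plates per genotype, and single plates set its count. Without WFS1-/- replicate 2-2, which left a lone WFS1-/- plate assumed to vary like the others, 1584 genes passed, against 56 without replicate 2-1 and 1 without WT replicate 1-2.

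As groups, 6 of 25 lists passed in astrocytes at the preset correlation and none with an estimated correlation. The latter setting also raised p where the estimate was below the preset. For the hypoxia response it was -0.049, and the unadjusted camera p went from 0.0291 to 0.145. The absence of calls therefore does not show that correlation between genes made the 6 calls. In the same plates the WFS1-/- cells had fewer UMIs, as given above, and astrocyte markers summed to 5993 and 6030 CPM in WT but 3114 and 4467 CPM in WFS1-/- plates. Depth and summed astrocyte markers thus differed along with the 6 passing lists. The sum includes GFAP, which was lower, and S100B, which was higher, as given above, so it does not set cell make-up. Reactive astrocyte genes were lower in WFS1-/- (15 of 18 negative, median -0.35, camera adjusted p = 0.0255; adjusted p = 0.695 with an estimated correlation), with the chemokine CCL2 at 121 and 15.6 CPM (-2.69), the complement inhibitor SERPING1 at -0.72 and CD44 at -0.62. Immediate early and dissociation genes were lower (12 of 17 negative, -0.86, adjusted p = 0.0255; adjusted p = 0.643 with an estimated correlation), with FOS, JUN (687 and 241 CPM, -1.47) and NR4A1, whose ratio was 7.93 (interval 2.06 to 67.7). Astrocyte factors acting on synapses were lower (12 of 15 negative, -0.43, adjusted p = 0.0397; adjusted p = 0.643 with an estimated correlation), with the BMP antagonist CHRDL1 (-2.57), TGFB2 (-1.40) and clusterin, CLU (-0.56). Integrated stress response genes were lower (17 of 23 negative, -0.55, adjusted p = 0.0461; adjusted p = 0.643 with an estimated correlation), with the pseudokinase gene TRIB3 (-2.38) and the serine synthesis gene PHGDH (-0.86).

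Higher in WFS1-/- astrocytes were p53 targets (14 of 19 positive, median 0.32, camera adjusted p = 0.0282; adjusted p = 0.643 with an estimated correlation), with the cell cycle inhibitor CDKN1A (0.65) and ZMAT3 (1.26), and glycolysis genes (12 of 18 positive, 0.34, adjusted p = 0.0335; adjusted p = 0.643 with an estimated correlation), with SLC2A3 and the neuronal enolase ENO2 (1.31). No member of these 6 lists passed over all genes, and adjusted over the list alone only CCL2 and FOS did. Every one of the 6 calls except p53 targets was lost without WFS1-/- replicate 2-1, where the adjusted p was 0.329 for the stress response, 0.329 for synapse factors, 0.775 for reactive genes, 0.338 for glycolysis and 0.0597 for immediate early genes. The p53 call was lost without WT replicate 1-2 (0.339) or WFS1-/- replicate 2-2 (0.565). Other plates ended calls too: WT replicate 1-1 for the stress response (0.053), synapse factors (0.18) and glycolysis (0.163), WT replicate 1-2 for the stress response (0.339) and synapse factors (0.061), and WFS1-/- replicate 2-2 for the stress response (0.235). WFS1-/- replicate 2-1 had only 21 passing cells, and its largest cell held 16.0% of its UMIs, against 53 cells and 3.92% in replicate 2-2. Cells expressing neuronal transcripts (cluster 2 below) made up 61.9% of WFS1-/- replicate 2-1 and 26.4% of replicate 2-2.

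The other 19 lists did not pass in astrocytes. Their median log2 fold changes and camera adjusted p were -0.41 and 0.0901 for glutamate uptake, where SLC1A2, a glutamate transporter, had -1.14, 0.57 and 0.0909 for the hypoxia response, -0.41 and 0.0966 for interferon response and MHC class I, -0.08 and 0.103 for the endoplasmic reticulum list, -0.21 and 0.125 for autophagy and lysosome, -0.13 and 0.139 for axon growth and guidance, -0.49 and 0.173 for forebrain identity, and 0.01 and 0.429 for hindbrain identity. For synaptic lists they were 0.20 and 0.336 (excitatory postsynapse) and -0.61 and 0.470 (presynapse), and the inhibitory list had an adjusted p = 0.483 with 2 genes of each sign. They were 0.27 and 0.336 for mitochondrially encoded genes, 0.04 and 0.336 for ribosomal proteins, 0.03 and 0.519 for nuclear oxidative phosphorylation, 0.04 and 0.778 for cholesterol synthesis, and -0.01 and 0.429 for extracellular matrix, where POSTN had 1.55 and COL3A1 passed over the list alone, as GABRB2 did in the inhibitory list. Median and test had different signs for calcium handling (-0.11, mean 0.10, adjusted p = 0.801), and median and mean for mitochondrial dynamics (0.02 and -0.04, adjusted p = 0.971) and the secretory list (0.11 with a mean just under 0, adjusted p = 0.971). Leaving out a plate made further calls. The endoplasmic reticulum list was lower without WT replicate 1-1 (0.00832) or WFS1-/- replicate 2-2 (0.00288), and without the latter autophagy (0.00288) and interferon response (0.00111) were lower too. The matrix was lower without WT replicate 1-1 (0.0111) and axon growth without WFS1-/- replicate 2-1 (0.0433). Mitochondrially encoded genes were lower without WFS1-/- replicate 2-1 (0.00333) but higher without replicate 2-2 (6.97e-05). With a replicate block the endoplasmic reticulum list (0.0175) and interferon response (0.0355) were lower, and with all wells ribosomal proteins were higher (0.0213).

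The genotype effect differed between cell types for PCSK1, CALB1, UBB and JUN. PCSK1 had 99.3 CPM in WT and 0 in WFS1-/- neurons but 108 and 112 CPM in WT and WFS1-/- astrocytes (adjusted p = 0.00428). CALB1 had 138 and 9.94 CPM in neurons and 2.29 and 22.6 CPM in astrocytes (log2 difference 6.82, SE 1.09, adjusted p = 0.00296). UBB had 36.7 and 820.5 CPM in neurons and 1403 and 1999 CPM in astrocytes (-3.94, SE 0.58, adjusted p = 0.00428), so that WT neurons stood apart from all other groups. JUN had 266 and 603 CPM in neurons and 833 and 283 CPM in astrocytes (-2.75, SE 0.52, adjusted p = 0.0182).

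These 4 were all that passed of 9575 genes by edgeR QL with BH adjustment, where 524 had an unadjusted p under 0.05 and DESeq2 called 20. CALB1 lost its call without astrocyte WFS1-/- replicate 2-2 (adjusted p = 0.403), UBB without neuron WFS1-/- replicate 2-2 (0.0752), and JUN without neuron WT replicate 1-2 (0.119), neuron WFS1-/- replicates 2-2 (0.0946) or 4-2 (0.0651), or astrocyte WT replicate 1-2 (0.0583). PCSK1 kept its call without any single plate. Without astrocyte WFS1-/- replicate 2-2, 132 genes passed. Without neuron WFS1-/- replicate 2-1, neuron WT replicates 3-1 or 3-2, or astrocyte WFS1-/- replicate 2-1 there were 8, 8, 9 and 8, and without neuron WFS1-/- replicate 2-2 there were 2.

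Of the lists, 7 differed between cell types at the preset correlation. A positive difference, meaning a change in astrocytes above that in neurons, was found for the presynapse (32 genes, median difference 0.48, camera adjusted p = 1.98e-04) and the excitatory postsynapse (23 genes, 0.78, adjusted p = 0.0356), with SYT4 at 3.63, RIMS2 at 2.55 and DLG2 at 2.69, none passing. These genes had few UMIs in WT and WFS1-/- astrocytes: 5 and 10 for SYT4, 19 and 29 for RIMS2, and 20 and 13 for DLG2. Only 12 presynaptic genes were tested in astrocytes alone, and 9 were negative (median -0.61, against -0.58 in neurons). Of 11 excitatory genes tested there, 8 were positive (0.20). The presynaptic difference therefore does not show that these genes kept their level in astrocytes. A negative difference was found for the integrated stress response (20 of 23 negative, -1.07, adjusted p = 2.08e-05), with TRIB3 (-4.23), SHMT2 (-1.92) and DDIT4 (-1.65), for chaperones of the endoplasmic reticulum (19 of 26 negative, -0.47, adjusted p = 0.0306), with HERPUD1 at -1.69, and for immediate early genes (-0.79, adjusted p = 0.0245), with JUN. It was also found for mitochondrially encoded genes (-0.42, adjusted p = 7.66e-09), with MT-ND1 at -1.39, and ribosomal proteins (63 of 78 negative, -0.40, adjusted p = 7.21e-10), with RPL13 at -1.05. With an estimated correlation the adjusted p was 0.309 for the endoplasmic reticulum list and 0.201 for the other 6. DESeq2's size factors placed the median of all genes at 0.02 where TMM placed it at -0.10, so differences of about this size depend on the scaling.

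For the other 18 lists the median difference and camera adjusted p were -0.63 and 0.0599 for reactive astrocyte genes, -0.67 and 0.0599 for hypoxia, -0.30 and 0.0924 for autophagy and lysosome, -0.50 and 0.105 for glutamate uptake, -0.80 and 0.121 for astrocyte factors acting on synapses, -0.31 and 0.121 for extracellular matrix, -1.59 and 0.134 for forebrain identity, -3.07 and 0.194 for hindbrain identity, -0.19 and 0.291 for nuclear oxidative phosphorylation, and -0.79 and 0.299 for interferon response and MHC class I. They were 0.13 and 0.393 for p53 targets, 0.04 and 0.401 for calcium handling, -0.22 and 0.441 for cholesterol synthesis, 0.04 and 0.918 for glycolysis and -0.50 and 0.944 for axon growth and guidance. The test pointed up although the median was negative for inhibitory synapses (median -0.14, mean -0.24, adjusted p = 0.121), the secretory list (-0.02, mean 0.24, adjusted p = 0.134) and mitochondrial dynamics (-0.05, mean 0.23, adjusted p = 0.697). Adjusted over the list alone, 2 presynaptic genes, 2 secretory genes and 1 gene each of calcium handling and interferon response had a positive difference. A negative difference was found in this way for 2 interferon response genes and for 1 gene each of the secretory, calcium handling, mitochondrially encoded and immediate early lists.

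The genotype effect also differed between the neuron batches. ONECUT1, a homeodomain factor of differentiating neurons, had 513 CPM in WT and 3.11 CPM in WFS1-/- neurons of batch 1 but 321 and 134 CPM in batch 2 (adjusted p = 3.63e-05), and FGF14, a regulator of sodium channels, 108 and 12.1 CPM but 100 and 122 CPM (adjusted p = 0.0430). In the other direction ZIC4, a zinc finger factor of the dorsal neural tube, had 0 and 59.6 CPM in batch 1 but 21.7 and 2.72 CPM in batch 2 (adjusted p = 0.0163), GDPD2 0 and 77.1 but 15.5 and 3.47 CPM (0.0145), PIFO, a cilium gene, 4.48 and 74.3 but 18.1 and 0.869 CPM (0.0145), and AHNAK 1.83 and 81.0 but 8.96 and 0.907 CPM (0.0370). The remaining named genes were EFNA5 (0.0451), AMY2B (0.0145), CDR1 (0.0370) and RAD51C (0.0443).

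By edgeR QL 68 of 8079 genes passed this comparison at a BH-adjusted p under 0.05, 20 with a more positive and 48 with a more negative effect in batch 2, and 854 had an unadjusted p under 0.05. With the dividing-like cells left out 12 genes passed, 6 of them among the 68, and ONECUT1 kept its call in all 15 alternatives. The count was 44 without WT replicate 1-1, 37 without WFS1-/- replicate 2-1, 37 without WT replicate 3-1, 44 without WFS1-/- replicate 4-1 and 135 without WFS1-/- replicate 4-2, and ZIC4, GDPD2 and PIFO lost their calls without WFS1-/- replicate 2-1 (adjusted p = 0.171, 0.404 and 0.578). The other named genes except ONECUT1 lost theirs when any of 2 to 6 plates was left out. A batch effect on a genotype is measured here from 2 plates per genotype and batch, which may be single cultures.

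Clustering separated the neurons largely by genotype and batch. Cluster 1 (143 cells) held 81.9% of the WT cells of batch 2, cluster 2 (141 cells) 90.3% of the WFS1-/- cells of batch 2, and cluster 3 (104 cells) 77.3% of WT and 52.2% of WFS1-/- cells of batch 1. Cluster 4 (52 cells) was dividing-cell-like: the mitotic genes NUSAP1, TOP2A and MKI67 were among its leading genes, with IFITM1, IFITM3, SPARCL1 and EDNRB. Its cells had 2708 CPM of the filament gene VIM and 698 CPM of the progenitor factor SOX2, and their neuron marker list summed to 1693 CPM against 10029 to 13387 CPM in the other clusters, although they had been sorted for a neuronal reporter. Of its 52 cells, 28 had a UMI of a dividing cell marker, so many were not shown to divide. A UMI of a progenitor, an astrocyte or a neuron marker was found in 50 cells each, so these counts do not set a type. In WFS1-/- replicate 2-1, 10 of 22 such cells had a dividing marker. Their dividing markers summed to 824 CPM, against 1844 CPM for progenitor and 1489 CPM for astrocyte markers.

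Cells of this dividing-like cluster made up 3.77%, 8.57%, 8.33% and 6.74% of the WT neuron plates and 43.1%, 38.9%, 0% and 9.72% of the WFS1-/- plates. The means ± SD were 6.85 ± 2.21% and 22.9 ± 21.3% (exact permutation within batch, p = 0.222 over 36 arrangements, 0.0556 being the smallest possible). In batch 1 the shares were 5 of 88 WT and 29 of 69 WFS1-/- cells, and in batch 2 they were 11 of 149 and 7 of 134. The plate at 0% had 62 cells, and its exact binomial interval reached 5.78%. The shares did not follow the dividing marker sums, which were 491 and 2270 CPM in WFS1-/- replicates 2-1 and 2-2 but 429 CPM in WT replicate 1-2 and 1438 CPM in WT replicate 3-1. Replicate 2-1 had 1033 CPM of progenitor and 862 CPM of astrocyte markers.

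**Figure D4:**
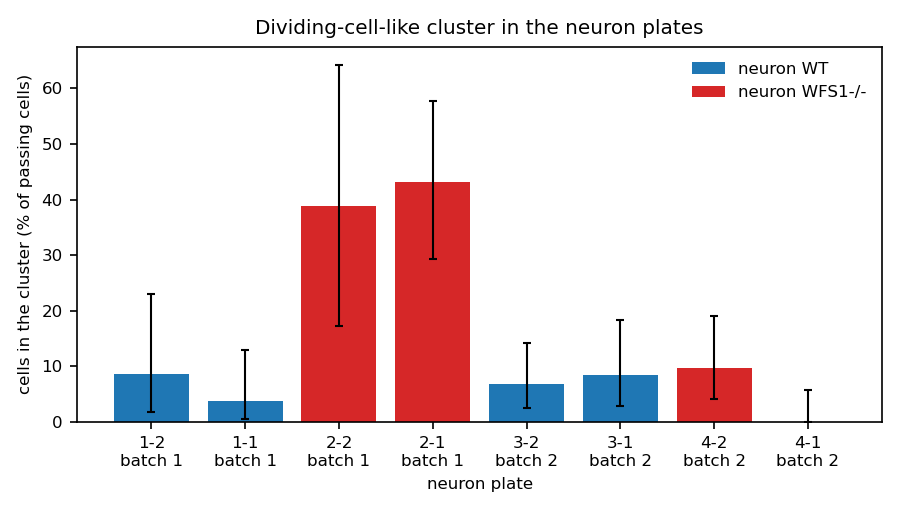
Percent of passing cells in the dividing-cell-like cluster in each neuron plate. Bars are exact binomial 95% intervals, which cover counting error only.

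Astrocytes formed 3 clusters. Cluster 1 (60 cells) led with COL3A1, COL1A2, CD74 and HLA-DRA and had the highest mesenchymal or fibroblast sum (7112 CPM), cluster 2 (59 cells) with SNHG3, SPP1 and the neuronal genes ELAVL3, MAPT and STMN2 (neuron list 4568 CPM), and cluster 3 (56 cells) with ACTG2, TAGLN, AQP4 and GABBR2. All clusters carried astrocyte markers, whose list summed to 4557, 5763 and 6225 CPM in clusters 1, 2 and 3. GFAP had 1331, 2301 and 2116 CPM in the same order. Cluster 3 also had 4775 CPM of mesenchymal or fibroblast markers. Cluster 1 made up 37.5% and 30.2% of the WT plates and 9.52% and 45.3% of the WFS1-/- plates, with means ± SD of 33.8 ± 5.17% and 27.4 ± 25.3% (exact permutation p = 1, 0.333 being the smallest possible).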

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

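Among the tests below, the count of shared ubiquitin reads and the mapping of the chromosome 6 stretch in astrocytes were chosen after the result was seen, as were the share of counts taken by mitochondrial and ribosomal genes and the tests without dividing-like cells, which were added to the fixed alternatives. Intervals of medians in this section are bootstraps over genes and do not cover the spread between plates or cultures.

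In 6 cases a plate stood far from the other 3 of its group, by a test in which chance marks about 1 in 20 groups and which was run on 54 sets of plate values. Neuron WT replicate 1-2 had a mitochondrial share of 3.58% (others 4.82% to 4.92%), and its largest cell held 22.9% of its UMIs (others 3.57% to 5.87%). Neuron WFS1-/- replicate 2-2, the shallowest plate, had a median of 1224.5 genes per cell (others 1631 to 1687.5) and a CNTN2 level of 196 CPM (others 44.0 to 52.9 CPM). Neuron WFS1-/- replicate 4-1 had 201 CPM of TCEAL2 (others 125 to 133 CPM) and 1.76 CPM of CSAG1 (others 0). The last value is a single UMI.

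The genotype effect differed between cell types for 4 genes and between neuron batches for 68 genes, by a test of the difference itself. Between cell types 7 gene lists also differed at the preset correlation, but 0 did with an estimated correlation (lowest adjusted p = 0.201). The adjusted p by edgeR QL was 0.00428 for PCSK1, 0.00296 for CALB1, 0.00428 for UBB and 0.0182 for JUN between cell types. Between batches it was 3.63e-05 for ONECUT1, 0.0145 for AMY2B, 0.0145 for GDPD2, 0.0145 for PIFO, 0.0163 for ZIC4, 0.0370 for CDR1, 0.0370 for AHNAK, 0.0430 for FGF14, 0.0443 for RAD51C and 0.0451 for EFNA5. Neurons and astrocytes were cultured, dissociated and sorted differently, so a difference between cell types cannot be told apart from a difference between these procedures.

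UBB was at 39.5 ± 21.9 CPM in WT and 877 ± 196 CPM in WFS1-/- neurons, while astrocytes of both genotypes had over 1000 CPM on average (1145 ± 55.6 and 1629 ± 1008). Reads moved from its paralogs were not the whole source, since the summed ubiquitin genes were higher in WFS1-/- by 811 CPM, with each WFS1-/- plate above each WT plate, but under the limits first set this test was undecided, so a part may be shared reads, and the rule that let the sum decide was settled after this was seen. Dividing-like cells were not the cause, since UBB had a log2 fold change of 4.45 without them, and neither was a copy gain around UBB, since its 8 tested neighbours had a median of -0.22 (interval -0.41 to -0.12). A UMI of UBB was found in 37 of 237 WT and 118 of 203 WFS1-/- neurons. Hypotheses that remain include a lower UBB supply particular to the WT neuron cultures, another difference between the lines and a true effect of genotype. The design does not separate these.

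A stretch of 15 neighbouring tested genes on chromosome 6, from ABCF1 to EHMT2 and including TUBB, FLOT1 and DDR1, was higher in WFS1-/- neurons in all 15 genes (median log2 fold change 1.2, interval 0.76 to 1.37). Its mean z was 3.31, against 1.88 for the next window elsewhere and at most 1.82 in 1000 shuffles of gene order (permutation p = 0.001, the smallest they can give). In batch 1 alone the top window, from ZSCAN16 to DDR1, had a mean z of 2.01, below the largest shuffled value of 2.38 (permutation p = 0.002), and in batch 2 alone that from TRIM39 to DDR1 had 3.09. The 15 tested genes before the stretch had a median of 0.35 (interval 0.07 to 0.64), so its edge on that side is not sharp. Dividing-like cells were not the cause (median 1.19 without them), nor was a single plate or batch (median 0.90 in the batch where it was lower, interval 0.60 to 1.32), nor a mapping change carried by the WFS1-/- line, which would raise the stretch in astrocytes too, where the median was 0.17 (interval -0.07 to 0.32). The difference between cell types had a median of -1.01 (interval -1.62 to -0.83). The fold is relative, so a copy change or a regulatory change acquired by the neuron cultures of either genotype may underlie it. This is a hypothesis that expression alone did not test.

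The synaptic lists were lower in WFS1-/- neurons together, with 45 of 52 genes negative and a median log2 fold change of -0.62, but with an estimated correlation none of the 3 passed (adjusted p = 0.100, 0.165 and 0.179). Dividing-like cells, whose summed neuron markers were below those of the other neuron clusters, could account for a part. Without them the median was -0.36 (interval -0.56 to -0.14), or 57.1% of the full value. Their share of the pattern cannot be told apart from an effect within neurons, although the GFP gate was meant to remove such cells. Mitochondrial and ribosomal transcripts taking up more counts were not the whole cause, as they lowered the share left for all other genes by a log2 change of only -0.0596 (-0.0837 in the pair of plates of a batch where it was largest). In batch 2, where dividing-like cells were no more frequent in WFS1-/-, the median was -0.33 against -0.72 in batch 1. A slower or different maturation of the WFS1-/- neurons is a biological hypothesis that remains open and was not tested.

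Chance was not excluded for the count of genes that passed between neuron genotypes. The real split gave 42 genes and any other at most 13, so 1 of 34 splits, the real one included, was as large. These splits include ones that were uneven over batch. Permuted within batch there are 36 arrangements, whose smallest share is 0.0556, above 0.05 even if each plate is a replicate of its own. Nor was chance excluded for the count of lists, where the real split gave 5, the highest other 8, and 17 of 34 splits as many. The split that follows batch could not be fitted, and only 1 other fitted split kept plates of the same leading title number together, with 2 genes and 7 lists. If such plates share a culture, the real split is 1 of 2, too few for a share under 0.05, and summing them left 2 genes.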

How the results depend on the processing

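The tests without dividing-like cells, with mitochondrial and ribosomal genes left out, with lists per batch and with list blocks were chosen after the result was seen. Depth and WFS1 values kept their direction and side of the threshold in all alternatives run, and among the values of named genes under alternatives, 1235 kept a call, 379 lost it, 964 had no call before or after, 71 gained one and 5 turned direction. For genes that passed in neurons 458 of 715 values kept the call, between cell types 59 of 72, between batches 153 of 224 and in the sort comparison 565 of 606. Those that turned were SNHG3 in astrocytes (main 5.56, -0.83 under the stricter filter, and -0.39 to 6.54 when a plate was left out, negative without WFS1-/- replicate 2-1) and, between batches without dividing-like cells, NES (5.14), PTPRZ1 (0.63) and NTRK2 (0.63). UBB and SPRY1 were the only named neuron genes kept in all 20 alternatives. In what follows the cause was not tested unless fewer plates, cells or genes are named.

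In neurons WFS1-/- against WT, where 42 genes passed, DESeq2 gave 81, no filter on low counts 104, no batch term 12, batch 1 alone 125, and the stricter cell filter, which left fewer cells, 8. Plates sharing the first number summed, with fewer units, gave 2, and leaving out a plate gave 24 to 41. In astrocytes WFS1-/- against WT, where 0 passed (251 unadjusted, and 0 by DESeq2), no filter gave 23 and leaving out a plate 0 to 1584. For the difference between neurons and astrocytes, where 4 passed, DESeq2 gave 20, no filter 27, the stricter filter 1, thinned cells 1, and leaving out a plate 2 to 132. Between the neuron batches, where 68 passed, the stricter filter gave 19, thinned cells 16, cells without the dividing-like cluster 12, and leaving out a plate 37 to 135. For WT astrocytes against WT neurons, where 2760 passed, the stricter filter gave 1760, thinned cells 1047, and leaving out a plate 1372 to 2952.

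Of the lists in neurons, 5 passed; an estimated correlation left 0, batch 1 alone gave 9, batch 2 alone 10, and leaving out a plate 6 to 11. Leaving out mitochondrial and ribosomal genes gave 2, but this removed 2 of the 5 lists from the test, and the third, the excitatory postsynapse, kept its fold (median -0.63 and -0.62). Of the lists in astrocytes, 6 passed; an estimated correlation left 0 and leaving out a plate 3 to 8. In the difference of effects 7 passed, and an estimated correlation left 0. For these passing lists fry gave an unadjusted p of 0.0023 to 0.0068 in neurons and 0.113 to 0.421 in astrocytes. In the difference of effects fry gave 0.0060 to 0.139. It also gave 2.05e-04 for calcium handling in neurons, a list that camera did not call. The share of dividing-like neurons differed by 16.1 points, and by 15.6 to 29.5 under the alternatives. The share of the mesenchymal astrocyte cluster differed by -6.44 points, and by 4.07 at Leiden resolution 1.0 and 2.24 with thinned cells.

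Replicate numbers do not pair the samples: correlations of plates sharing a number were -0.030, 0.010 and -0.066. With a replicate block 23 genes passed in neurons and 0 in astrocytes (edgeR QL, 162 unadjusted, and 0 by DESeq2 without a block), with 4 and 7 lists. The alternative without high-UMI or high-mitochondrial wells removed 0 wells and gave no value, and the stricter filter gave no astrocyte share. Depth limits low genes most in neuron WFS1-/- replicate 2-2, with 64748 UMIs from 18 cells.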

Other observations

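All genes named in the next paragraphs were chosen after their values were seen, as was the test without dividing-like cells.

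Further genes that passed between neuron genotypes by edgeR QL with BH adjustment were mostly lower in WFS1-/-. ONECUT2, a homeodomain factor of differentiating neurons, fell from 214 to 47.4 CPM (log2 fold change -2.14, SE 0.38, adjusted p = 0.00165, with -2.60 and -1.88 in batches 1 and 2), RPRM, a cell cycle inhibitor, from 190.1 to 43.8 CPM, and SMC1A, a cohesin subunit, from 687 to 311 CPM (adjusted p = 0.00267). The adhesion gene LRRC4C, which encodes a partner of netrin G at synapses, fell from 220.3 to 78.3 CPM, the neuronal actin-capping gene TMOD2 from 334 to 136 CPM and ANK2, an ankyrin of axons, from 519 to 267 CPM. MYL6, a myosin light chain, rose from 7666 to 12786 CPM. Without WT replicate 3-1 the adjusted p was 0.0568 for ONECUT2, 0.0563 for RPRM and 0.0560 for MYL6, while LRRC4C, TMOD2 and ANK2 lost their calls when any of 7, 6 and 6 plates was left out.

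Some genes of progenitors and glia were among the 68 whose genotype effect differed between the neuron batches. No gene list was tested for this difference, so they are given as single genes. Levels in WT and WFS1-/- neurons were 399 and 1751 CPM in batch 1 but 604 and 226 CPM in batch 2 for CLU, which encodes clusterin, 61.5 and 259 but 68.3 and 32.4 CPM for NES, a progenitor filament gene, and 68.0 and 491 but 103 and 33.2 CPM for NTRK2, a neurotrophin receptor. PTPRZ1, a phosphatase gene of glia and progenitors, had 24.2 and 239 but 83.0 and 54.0 CPM. The calls of NES and PTPRZ1 were lost when any of 4 and of 2 plates was left out. Without dividing-like cells the difference between batches in log2 units went from -3.55 to -0.97 for CLU, and from -4.53 to 0.63 for NTRK2, so these cells may carry most of it. SOX4, a factor of young neurons, moved the other way (11208 and 5486 but 7068 and 14391 CPM, adjusted p = 3.98e-05) and kept its call in all 15 alternatives. GRIA2 had 519 and 129 CPM in batch 1 but 797 and 661 CPM in batch 2 (adjusted p = 0.0374), a call lost in 8 of the alternatives, with an adjusted p of 0.643 without dividing-like cells and 0.0658 to 0.489 in the others that ended it.

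HLA-DRA, a gene of MHC class II antigen presentation, had 639.8 CPM in the astrocyte cluster richest in fibroblast transcripts, 2.47 CPM in the cluster with neuronal transcripts and 72.6 CPM in the remaining cluster. Microglia and blood markers summed to 0.439 CPM in WT and 0 CPM in WFS1-/- astrocytes.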
